A study of Mus musculus with 8 samples.

How the data were processed

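MeRIP-seq libraries were made from total RNA of left ventricle of C57BL/6 mice, with 200 µg of RNA per group, per the labels' protocols. RNA was selected for poly(A) and fragmented before the pulldown, and 50 bp single reads were sequenced on an Illumina HiSeq. The samples fell into 8 groups of 1 library: input and MeRIP for sham, MI, MI with aavgnp and MI with aavFto. Reads were aligned with STAR 2.5.3a to mm10, per the submitters' processing notes. The peak caller, its settings and the thresholds of the tables are not given in the sources used here.

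The analysis started from 2 deposited tables of peaks, 1 for each comparison. Per the file headers, each row gave the blocks of a peak on the genome, its strand and a gene ID. The deposited score column holds the enrichment p-value of the peak. The authors also gave the enrichment p and FDR as log10 values, and a fold enrichment over input, which is a linear ratio. The deposited change between the groups is on a log2 scale, with its differential p and FDR as log10 values, per the file headers. How the authors scaled the libraries before these values were made is not given in the sources used here. The log10 values were converted to p and FDR for printing. The log2 change was read as the first-named group over the second, an assumption from the order of the groups in the tables' names. The second group in the name of the aavFto table is given there as null, and it was read as aavgnp because the labels tie the aavFto and aavgnp libraries to that table. Library totals were not analysed here, so depth per library is unknown and no interval that needs it is given. All p-values and FDRs are the authors' own, and none was computed across peaks or genes, which are not replicates.

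Gene IDs were matched to symbols in a RefSeq gene table of GRCm38.p6, the same assembly as mm10. All 105 peaks with an ID in the MI table and all 449 in the aavFto table matched and overlapped the span of their gene. The 11 and 16 peaks without an ID were kept for counts of peaks and left out of counts of genes, and genes at their positions were taken from that table. Coordinates are 1-based, on mm10. The gene table holds gene spans and no exons or sequence, so the planned assignment of peaks to UTR, coding sequence or stop codon and the planned search for the DRACH motif were not run. The position of the peak centre along the gene span was computed in their place.

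Shares of positive peaks were given with exact (Clopper-Pearson) 95% intervals. A gene was represented by its peak of largest absolute log2 change. For 12 gene lists fixed before the data were examined, the median change of the list's genes was placed among 10000 random lists of the same size, drawn from the genes of the same table and matched in 5 bins of fold enrichment. This was repeated with 20 sets of random lists, and the mean percentile over the sets is given. The repeat was added after seeing the data, because the call of the sarcomere list matched on enrichment p changed with the random draw. Lists with fewer than 3 genes in a table got no percentile. A list was called when it lay outside the central 95% of random lists, which describes these libraries and is not a test across animals. Peaks of the 2 tables were counted as shared when their blocks overlapped by at least 1 bp on the same strand. Signs of shared genes were compared with 10000 random re-pairings. The number of tests behind each table was estimated from the ratio of FDR to p under the Benjamini-Hochberg rule. The search stopped at a set limit, and multiples of a fitting number can also fit, so no upper bound follows.

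The genes named in the text were chosen by a rule set before the data were examined. It took, per comparison, the 10 genes with the largest positive and the 10 with the largest negative change, up to 4 genes of each list, up to 12 genes in both tables, and Fto with the m6A machinery. The rule spoke of peaks past the authors' threshold, and since the tables also list peaks with no differential call it was applied to all listed peaks. Not every gene that the rule selects is reported here. Every peak past a differential FDR of 0.05 was named in addition, a choice made after seeing the data, as was naming the long noncoding and ribosomal RNA peaks. The alternatives tried were stricter FDR, minimum change, minimum enrichment, genes in place of peaks, removal of sex and mitochondrial chromosomes, the overlap rule, the mean over a gene's peaks and other matching of random lists.

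The list and test-number scripts were tested on simulated data. With no shift, 2 of 50 lists of 10 genes were called among the 77 genes of the MI table, and 2 of 50 among the 271 genes of the aavFto table. With a shift of 2 on the log2 scale, 42 of 50 and 50 of 50 were called. Smaller shifts and lists of other sizes were not simulated, so sensitivity to the mostly smaller changes of the aavFto table was not checked. The range for the number of tests held the true value in 19 of 20 simulated tables. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.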

Results

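N6-methyladenosine (m6A) is a methyl mark on adenosines of RNA, and FTO is an enzyme that removes it. MeRIP-seq was carried out on left ventricle of C57BL/6 mice, harvested 1 week after surgery. In this assay fragmented RNA is pulled down with an antibody against m6A and sequenced beside RNA that did not go through the pulldown (the input). The 8 libraries fell into 4 groups with 1 input and 1 MeRIP library each: sham-operated hearts, hearts after myocardial infarction (MI), infarcted hearts labelled aavgnp and infarcted hearts labelled aavFto. The aavFto hearts are taken to have received Fto by vector and the aavgnp hearts to be their comparison group, since the labels expand neither name. The authors deposited a table of m6A peaks for each of 2 comparisons, MI against sham and aavFto against aavgnp, on the mouse build mm10. Each peak carried an enrichment over input and a log2 change between the 2 groups with a p-value and a false discovery rate (FDR). No group had a replicate, so no difference reported here has a replicate check, and the authors' p-values compare the libraries, not the conditions. The file headers do not state the sign of the log2 change, which was read as MI over sham and aavFto over aavgnp, and the opposite reading would turn every direction of the table concerned. The read depth of the libraries is unknown, and all intervals cover counting error only.

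The first comparison addressed how m6A in the ventricle differed between infarcted and sham-operated hearts. Single peaks in Col1a1 and Col3a1, and peaks in Nppa, Myh7 and Ankrd1, rose after MI, and single peaks in Myh6 and Atp2a2 fell. Transcript levels and tissue make-up were not analysed here for either comparison. A change in methylation can therefore not be told apart from a change in these. The authors' deposited table gave a log2 change of 4.31 (FDR 2.09e-09) for a peak in Col1a1, a chain of type I collagen, and 7.17 (FDR 0.014) for a peak in Col3a1, the chain of type III collagen. A peak in Nppa, which encodes atrial natriuretic peptide, rose by 4.52 (FDR 9.12e-06) in the authors' deposited table. The largest fall past the threshold in the authors' deposited table was -3.93 (FDR 0.029) in Atp2a2, the calcium pump of the sarcoplasmic reticulum, and the other was -2.56 (FDR 0.027) in Myh6, the adult myosin heavy chain of the mouse ventricle. A longer and stronger Atp2a2 peak, of 750 nt, stood at -1.18 (FDR 0.33) in the authors' deposited table.

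The table held 116 peaks in 77 named genes, 11 of the peaks without a gene ID. Of these, 98 were positive and 18 negative, a positive share of 84.5% (exact 95% interval 76.6 to 90.5). The median log2 change was 1.92 (interquartile range 1.24 to 3.18). At an FDR of 0.05 in the authors' test 17 peaks passed, 15 positive and 2 negative, and 30 had an unadjusted p under 0.05, 25 positive and 5 negative. Overlapping peaks merged into 1 locus each left 12 loci past the FDR. The smallest absolute log2 change was 1.01, so the table was restricted to changes of at least 1. Within the numbers of tests tried, its FDR values fit 236 to 237 tests or 464 to 476 tests. Larger numbers were not tried, so neither range is an upper bound. The shares therefore describe the listed peaks and not all peaks that were tested. With the peaks ranked by enrichment p and split into 5 groups, the positive share was 66.7% in the strongest and 100% in the weakest. Weak peaks of unrelated genes had like enrichment values, with a fold enrichment of 70.8 for peaks in Hspb6, Col4a1 and Ndufb8. Whether the positive changes of such weak peaks come from low read counts was not tested.

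All 10 listed genes of the extracellular matrix list had a positive largest change, and 2 of them, Col1a1 and Col3a1, had a peak past the FDR. Their median was 4.72, at percentile 99.99 of random lists of as many genes from the same table, matched on fold enrichment. Among the 8 members without a peak past the FDR, the authors' deposited table gave 6.58 for Postn, which encodes the matrix protein periostin, 6.45 for Sparc, 5.64 for Col1a2 and 5.12 for Bgn. The enrichment log10 p of these peaks lay between -5.13 and -3.97, so the caution on weak peaks applies. Serpinh1, a collagen chaperone, stood at 4.28 with an FDR of 0.52 in the authors' deposited table. The Col1a1 peak lay on chromosome 11 at 94950885 to 94951575 and the Col3a1 peak on chromosome 1 at 45338738 to 45339973, each over 3 exon blocks.

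The 3 listed genes of the fetal and hypertrophic list, Nppa, Myh7 and Ankrd1, each had a peak past the FDR, all positive. Over each gene's largest change the list's median was 4.42, at percentile 93.9. For Myh7, at 4.42 (FDR 0.5), and Ankrd1, at 3.47 (FDR 0.23), the authors' deposited table gave that change at a peak not past the FDR. Myh7, the myosin heavy chain of the fetal mouse ventricle, had 5 peaks past the FDR. The authors' deposited table gave them changes of 4.35, 3.91, 3.80, 3.63 and 2.70. The strongest of them by FDR, 1.26e-05 in the authors' deposited table, spanned chromosome 14 from 54971696 to 54972783. Ankrd1, a stress-responsive protein of the sarcomere, rose by 2.40 (FDR 4.79e-04) and 2.36 (FDR 0.032) at 2 peaks of the authors' deposited table. Another 5 peaks without a gene ID lay inside Nppa on chromosome 4, and 4 of them passed the FDR, with 6.06, 6.06, 4.39 and 4.39 in the authors' deposited table and 1 peak of each value on either strand. The remaining 1, at 148001766 to 148001884, had the largest change of the authors' deposited table, 7.21, with an FDR of 0.16. Mhrt, a noncoding transcript opposite to Myh7, had a peak with a change of 2.13 (FDR 0.036) in the authors' deposited table. That peak overlapped a Myh7 peak on the other strand, and reads of Myh6 and Myh7, which are close paralogs, could also be shared, so the split among these 3 genes is uncertain.

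The sarcomere list had 10 listed genes, 7 positive and 3 negative, with a median of 1.31 at percentile 6.84. Its 3 genes with a peak past the FDR were Myh7, Ankrd1 and Myh6, and the authors' deposited table placed Mybpc3 at -2.13 (FDR 0.64) and Myom1 at -1.58 (FDR 0.74). The calcium handling list had 3 listed genes, and beside Atp2a2 the authors' deposited table gave -1.67 for Hrc and 3.36 for Casq2, the calcium store protein calsequestrin. Its median of -1.67 stood at percentile 4.07, and with the mean over each gene's peaks the median was -0.18 at percentile 11.8. The mitochondrial and fatty acid list had 4 positive and 3 negative genes, none past the FDR, at percentile 14.1, and the authors' deposited table gave -1.93 for Ogdh, -1.85 for Lpl, -1.33 for Cox7a1 and 1.98 for Fabp4. With the mean over each gene's peaks this list's median turned from 1.28 to -0.45, at percentile 0.387, outside the central 95% of random lists.

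Markers of other cell types were positive in this comparison, with none past the FDR. By largest change 67 of the 77 named genes in the table were positive (87.0%), so a positive sign does not set these markers apart. Their lists had too few listed genes for a percentile. The authors' deposited table gave 4.39 for Clu and 2.58 for Pdgfrb of the fibroblast list, 3.51 for Apoe and 2.16 for Ctsd of the macrophage list, and 2.56 for Eng and 1.65 for Cdh5 of the endothelial list. The other Clu peaks stood at 3.12, 2.48 and 2.04 in the authors' deposited table. All 5 listed genes of the cell death and stress list were positive, none past the FDR, with a median of 1.73 at percentile 44.9, and the authors' deposited table gave 2.91 for Hsp90ab1, 2.20 for Hspb7, 1.73 for Hsp90b1 and 1.61 for Hspa5. Dsp, a desmosomal protein, stood at -1.64 and Tle5 at -1.39 in the authors' deposited table. No gene of the m6A machinery, cell cycle or erythroid lists had a listed peak, and Fto had none.

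**Figure D1:**
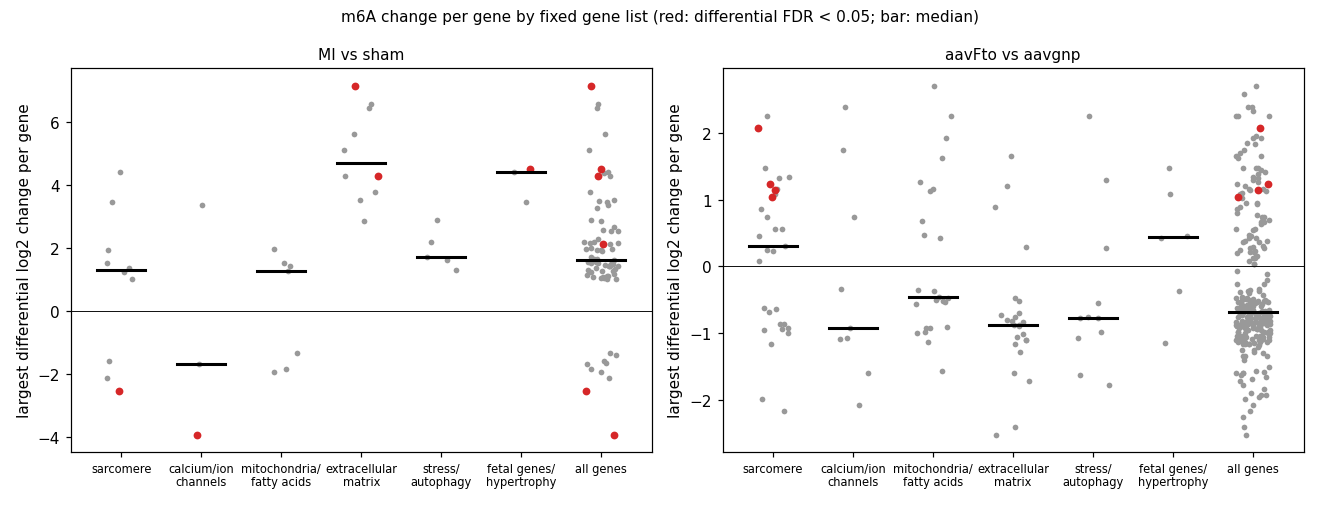
Log2 change per gene, taken from the peak of largest absolute change, for 6 fixed gene lists and for all named genes, in MI against sham and in aavFto against aavgnp. Each point is 1 gene, a red point has an FDR under 0.05 at that peak in the authors' test, and a black bar is the median: 4.72 for the matrix list after MI, and 0.31 for the sarcomere list with aavFto.

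The second comparison addressed how m6A in infarcted hearts differed between the aavFto and aavgnp groups. All peaks past the FDR rose, and they lay in 5 sarcomere genes and in the ribosomal RNA locus. Those in the 5 genes were 633 to 3564 nt long, against a median of 181 nt over all listed peaks. They are therefore long regions of a transcript and not single m6A sites. The authors' deposited table gave 1.24 (FDR 1.58e-11) for a peak over Tnnt2, cardiac troponin T, 2.07 (FDR 0.031) for Tcap, the cap protein of titin, and 1.15 (FDR 0.0065) for Myl2, the ventricular regulatory light chain. Myh6 rose by 1.05 (FDR 8.13e-10) and 0.70 (FDR 0.0021) at 2 peaks, and Mybpc3, cardiac myosin binding protein C, rose by 1.04 (FDR 0.031), in the authors' deposited table. The other 2 peaks past the FDR, with changes of 1.33 (FDR 3.02e-05) and 1.44 (FDR 0.043) in the authors' deposited table, had no gene ID and lay at Rn18s-rs5 on chromosome 17.

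The table held 465 peaks in 271 named genes, 16 of the peaks without a gene ID. Most listed peaks were negative: 152 were positive and 313 negative, a positive share of 32.7% (exact 95% interval 28.4 to 37.2). With the sign of the table turned the share would be 67.3%. The median log2 change was -0.61 (interquartile range -0.90 to 0.30). At an FDR of 0.05 in the authors' test 8 peaks passed, 8 positive and 0 negative, and 20 had an unadjusted p under 0.05, 18 positive and 2 negative. None of the 313 negative peaks passed, so no fall was called. Some peaks of unrelated genes carried the same enrichment values. Peaks in Mprip, Hsp90ab1 and Col4a1 each had a fold enrichment of 50.6 and a log10 p of -4.2. Whether the negative changes of such weak peaks come from low read counts was not tested directly. A comparison of weak and strong peaks within genes, given below, could not decide it. The positive share depended on the strength of the peak. With the peaks ranked by enrichment p and split into 5 equal groups of 93, it was 63.4% in the strongest group, then 48.4%, 28.0% and 11.8%, and 11.8% in the weakest group.

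**Figure D2:**
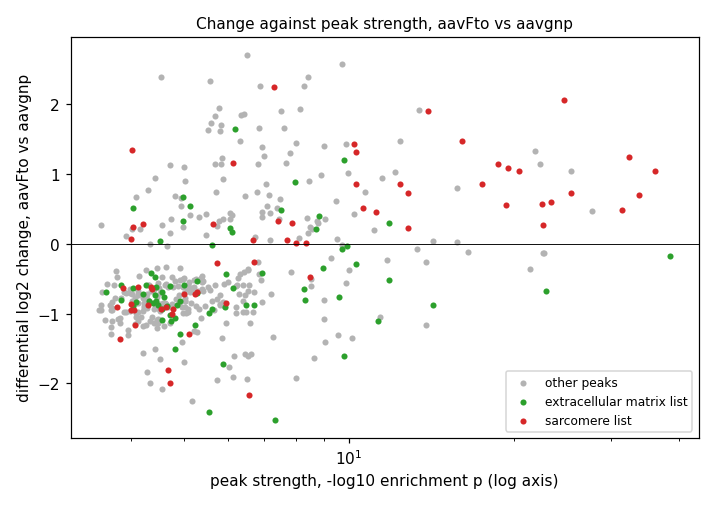
Log2 change between aavFto and aavgnp (vertical axis) against peak strength, the authors' enrichment p as -log10 on a log axis (horizontal axis), for each of the 465 listed peaks. Peaks of the sarcomere list are red and peaks of the matrix list green, and the positive share was 63.4% in the strongest 93 peaks and 11.8% in the weakest 93.

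The sarcomere list had 31 listed genes, 19 positive and 12 negative, and 5 had a peak past the FDR. Its median of 0.31 stood at percentile 99.8 of random lists from the same table matched on fold enrichment. Matched instead on the enrichment p of each gene's strongest peak, a choice made after seeing the data, it stood at percentile 97.51, on the edge of the central 95%. The Tnnt2 peak covered 17 exon blocks on chromosome 1 from 135836394 to 135852268, the Mybpc3 peak 32 blocks on chromosome 2 from 91118204 to 91135443, and the Tcap peak 2 blocks on chromosome 11 from 98383841 to 98384953. The most negative members in the authors' deposited table were Flnc at -2.16 (FDR 0.71) and Ttn, the giant protein titin, at -1.99 (FDR 0.71). Another Myh6 peak carried the gene's largest change, 2.25, with an FDR of 0.60 in the authors' deposited table.

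Of 25 listed matrix genes, 21 were negative and 4 positive, and none passed the FDR. Their median of -0.87 stood at percentile 4.15, inside the central 95% of random lists. The authors' deposited table gave -2.52 for Serpinh1, -2.41 for Fn1, which encodes fibronectin, -1.72 for Col4a1 and -1.60 for Bgn. Col1a1 was among the 4 positive members, at 1.65 in the authors' deposited table. The fibroblast list had 3 positive and 7 negative genes at percentile 67.0, the macrophage list 1 and 5 at percentile 37.5 and the endothelial list 0 and 4 at percentile 63.7, with no gene past the FDR. Of the fibroblast list, the authors' deposited table gave -2.25 for Fstl1, -1.3 for Sfrp2, -1.06 for Igfbp4 and 0.95 for Gsn. Of the macrophage list, the authors' deposited table gave -1.92 for the cathepsin Ctsb and 1.14 for Apoe, whose unadjusted p was 0.024, and Cdh5 of the endothelial list was at -0.69.

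The calcium handling list had 3 positive and 6 negative genes at percentile 5.81, none past the FDR. The authors' deposited table gave 2.39 for Atp2a2 and 1.74 for Gja1, the gap junction protein connexin 43, against -2.08 for Trdn and -1.60 for Jph2. With the mean over each gene's peaks the calcium list stood at percentile 51.7, with a median of -0.51 in place of -0.93. The mitochondrial and fatty acid list had 10 positive and 15 negative genes at percentile 88.2, none past the FDR, and the authors' deposited table gave 2.71 for Atp5b, 1.93 for Ckm and 1.63 for Cox7a1. The fetal list had 4 positive and 2 negative genes at percentile 90.2, with Myh7 at 1.47, Jun at -1.15, Ankrd1 at 1.09 and Acta1 at 0.46 in the authors' deposited table. The cell death and stress list had 3 positive and 8 negative genes at percentile 28.1, with Hsp90ab1 at 2.26, Lamp1 at -1.77, Nfe2l1 at -1.63 and Hspb7 at 1.30 in the authors' deposited table. No member of either list passed the FDR.

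Outside the lists, the authors' deposited table gave 2.58 for Cyb5r3, 2.39 for Eef1a2, 2.33 for Cenpb and 1.95 for Golga4, and -1.95 for Rrbp1, -1.93 for Cavin1 and -1.90 for Plec, none past the FDR. Of the m6A machinery the authors' deposited table listed Prrc2a, at -0.84 (FDR 0.71). Fto had no listed peak, and its transcript level was not analysed here, so the tables hold no check of the vector. The 1 listed erythroid gene, Hbb-bs, stood at 0.67 in the authors' deposited table, and no cell cycle gene was listed.

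The 2 comparisons were then set side by side. The positive share was 51.8 percentage points higher in MI against sham than in aavFto against aavgnp. In the strongest of 5 groups by enrichment p the shares were 66.7% after MI and 63.4% with aavFto, a gap of 3.23 points. The MI share came from 24 peaks with changes of at least 1 (exact 95% interval 44.7 to 84.4). The aavFto share came from 93 peaks without that restriction (52.8 to 73.2). These shares are thus unlike and imprecise, and do not show that the contrast vanishes among strong peaks. With changes of at least 1 in both tables, which matched the restriction of the first, 42.0% of 131 peaks were positive with aavFto (exact 95% interval 33.4 to 50.9), and the gap was 42.5 points. With the sign of the aavFto table turned the gap was 17.2 points, and with that of the MI table turned it was -17.2 points, which reverses the order. Among peaks past the FDR the order was not the same, with 15 of 17 positive after MI and 8 of 8 with aavFto. It also rests on the assumed signs. With the aavFto table turned 0 of 8 would be positive, and with the MI table turned 2 of 17.

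Of the 77 genes in the MI table, 74 also had a peak in the aavFto table, and 45 of these had largest changes of opposite sign (29 if the sign of 1 table were turned). Atp2a2 was at -3.93 after MI and 2.39 with aavFto, and Myh6 at -2.56 and 2.25, in the authors' deposited table of each comparison. With aavFto the FDR was 0.71 for this Atp2a2 peak and 0.60 for this Myh6 peak. Of the other Atp2a2 peaks with aavFto, that at -1.16 was negative and the rest were positive. Col3a1, Postn, Sparc, Col1a2, Bgn, Col4a1, Serpinh1 and Nppa were positive after MI and negative with aavFto, as were 38 genes in all, and 7 genes were the reverse. Col1a1, Myh7 and Hsp90ab1 were positive in both tables, as were 27 genes in all, and 2 genes were negative in both. The largest changes of some genes were at different sites in the 2 tables. Of 72 genes with an aavFto peak that overlapped their largest MI peak, 40 had opposite signs there (32 if the sign of 1 table were turned). This count was not set against re-pairings. Some of the overlapping aavFto peaks were far longer than the MI peak, as for Col1a1, with 3923 nt against 361 nt. At these overlapping peaks the authors' deposited table for aavFto gave -0.18 for Col1a1, -0.03 for Postn, -0.07 for Col4a1, -0.29 for Col1a2, -0.42 for Sparc and 0.24 for Hsp90ab1, all with an FDR of 0.71. Random re-pairing of the 74 genes' values gave a median of 39 genes of opposite sign (95% range 33 to 45), and 95.8% of re-pairings gave fewer than 45, so the count was not beyond that range. By position, 122 pairs of peaks overlapped on the same strand, of which 77 had opposite signs (45 if the sign of 1 table were turned). Only 53 pairs overlapped by at least 50% of both peaks, 34 of them of opposite sign. No pair had an FDR under 0.01 in both tables. Whether the MI and aavgnp libraries come from separate animals is not stated.

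**Figure D3:**
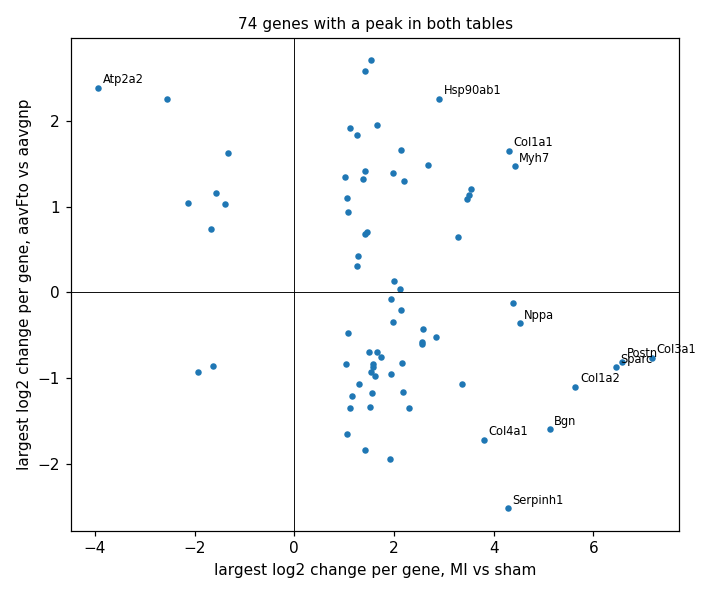
Largest log2 change per gene after MI (horizontal axis) against that with aavFto over aavgnp (vertical axis) for the 74 genes with a peak in both tables, with names given for the 12 of largest summed absolute change. Each point is 1 gene, 38 lie in the lower right (positive after MI, negative with aavFto) and 27 in the upper right.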

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

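Merging of peaks, groups by strength, matching on enrichment p, the filter on size of change in both tables, turned signs and the pairing of peaks at 1 site were chosen after seeing the data. Of 78 alternatives over 23 results, 4 removed no peak that the result counts, 52 left the direction and call in place and 2 more lay on a bound of the central 95%. With a differential FDR under 0.01 the positive share was 100% in both tables, a reversal for aavFto against aavgnp, the gap between the tables was 0 points, and the number of peaks past the threshold was 9 after MI (from 17) and 5 with aavFto (from 8), since only strongly called peaks stay under that setting. The aavFto share reversed to 63.4% in the strongest 93 peaks, moved to 11.8% in the weakest 93 and to 42.0% with changes of at least 1, which put the gap at 42.5 points, and the gap was 3.23 points in the strongest peaks of each table; the cause was not tested by these settings. If the sign of 1 table were turned, the gap would be 17.2 points (aavFto turned) or reverse to -17.2 points (MI turned), and the share of genes of opposite sign would reverse to 39.2%. The matrix list with aavFto was called when matched on enrichment p, at percentile 0.708, but stood at percentile 25.3 with the mean over each gene's peaks. The sarcomere list with aavFto lay between percentiles 97.2 and 97.7 over 20 sets matched on enrichment p, so that call is open, and the matrix list lay between 2.27 and 3.03 with unmatched lists. Another 6 alternatives brought a call, in the calcium handling, fetal and mitochondrial lists after MI and the mitochondrial list with aavFto; the mitochondrial list after MI went to percentile 0.387 and a median of -0.45 with the mean over each gene's peaks. The 4 that removed none, and so say nothing, were a minimum enrichment of 2 in both tables, and in the MI table a minimum change of 1 and, for peaks past the FDR, leaving out the ribosomal RNA locus. No peak pair was left at an FDR under 0.01 in both tables. The transcript location and DRACH alternatives were not run. No paired analysis was possible because each group had 1 library. Depth per library, which limits weak peaks most, is unknown.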

Other observations

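The tests of matched peak strength and of strand were chosen after the result was seen. Noncoding RNA also carried listed peaks. In the authors' deposited table for MI, 2 peaks of Neat1 stood at 1.58 and 1.29, and 3 peaks without a gene ID at its position at 1.55, 1.27 and 1.26. With aavFto the authors' deposited table gave Neat1 4 peaks, 3 of them negative, the lowest at -0.87, and 5 negative peaks without a gene ID at its position, the lowest at -0.90. Many of these overlapped one another, and none passed the FDR. Malat1 was listed with aavFto, where the authors' deposited table gave -0.78, 0.81 and -0.61. At the ribosomal RNA locus of chromosome 17 the authors' deposited table gave -1.14 (FDR 0.11) and -1.01 (FDR 0.20) after MI. With aavFto the 4 peaks at this locus in the authors' deposited table were the 2 that rose and 2 at 1.05 (FDR 0.089) and -0.02 (FDR 0.71). The RNA had been selected for poly(A), per the labels' protocols, and why ribosomal peaks were listed was not tested.

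More peak centres lay in the last than in the first 20% of gene spans. The peak centre fell in the last 20% of the gene span for 59.0% of peaks in the MI table (exact 95% interval 49.0 to 68.5) and 53.2% in the aavFto table (48.5 to 57.9), against 5.71% and 6.46% in the first 20%. Spans include introns. Several genes held peaks of both signs. Of 94 genes with 2 or more peaks in the aavFto table, 49 had both signs, 32 were all negative and 13 all positive. With changes of at least 1, the restriction of the MI table and a setting chosen after the result was seen, 1 of 11 such genes had both signs with aavFto and 2 of 16 after MI. The mixed genes after MI were Atp5b, with -1.48, -1.40 and 1.54 in the authors' deposited table, and Hrc, with -1.67 and 1.31.

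The first pattern was the trend of sign with peak strength in the aavFto table, where the positive share fell by 51.6 points from the strongest to the weakest 93 peaks. Sarcomere genes hold many strong peaks, but without that list the gap was still 46.8 points, which argues against it as the whole cause. Read depth or the way the change was estimated may instead push weak peaks of any gene to negative values, and within 94 genes the weakest peak had the lower change in 59.6% (exact 95% interval 49.0 to 69.6). That interval reaches just below an even split and also holds a clear excess, so it decides nothing, although the rule set before the test had read any interval that included 50% as evidence against. The MI table ran the other way, with 66.7% positive in the strongest of 5 groups and 100% in the weakest, but it lists only changes of at least 1 and comes from other libraries, so both this explanation and a biological difference between aavFto and aavgnp stay open, the latter untested.

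The second pattern was the contrast of positive sarcomere and negative matrix genes with aavFto. Peak strength may account for the sarcomere part, since matched on enrichment p its median stood at percentile 97.51 and its sets of random lists fell on either side of the upper bound of the central 95%. For the matrix part the same matching gave percentile 0.708, below the central 95% in every set. It used the p of each gene's strongest peak, while the change could come from a weaker peak. For Col4a1 the change of -1.72 lay at a peak with log10 p of -5.88, and its strongest peak had -9.7. The matching therefore cannot decide whether strength is the cause. The list was not called with its planned matching and stood at percentile 25.3 with the mean over each gene's peaks. The matrix part itself is thus not secure. A change in transcript level or tissue make-up could move all peaks of a gene together, and 63.0% of peak pairs within genes shared their sign, against 52.2 to 64.6% in shuffles within strength bins. That value lies in the upper part of the range, so it cannot exclude such a shift, although the rule set before the test would have read any value within the shuffles as excluding it.

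The third pattern was the repeat of peaks on both strands. All 6 opposite-strand pairs that covered each other by at least 90% had log2 changes within 0.05, the largest gap being 0.014, at Nppa, Neat1 and Srsf4. Reads counted without regard to strand would give such values, and such pairs would then be 1 measurement each. The overlapping Mhrt and Myh7 peaks, at 2.13 and 3.80 after MI, were not among the 6 pairs. Under such counting these genes could not be separated where they overlap. No biological explanation was tested for this pattern.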
